A study of Homo sapiens with 6 samples.

How the data were processed

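RNA was measured in 6 libraries of SNU216 cells, an established human gastric cancer cell line. Per the labels' protocols, 3 libraries came from cells transfected for 48 h with a control siRNA (siControl) and 3 from cells transfected for 48 h with an siRNA against the oxytocin receptor gene OXTR (siOXTR). RNA was taken up in Trizol and libraries were prepared by a BGISEQ-500 protocol, per the labels' protocols. The labels number the libraries 1 to 3 in each group and do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The siRNA sequences are not given in the sources used here.

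The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), per the file headers, with 1 value per gene and library, rounded to 2 decimals. The genome build was GRCh38.p13, per the submitters' processing notes. The aligner, the quantifier, the annotation and any filter are not given in the sources used here. All 6 files list the same 17318 genes by Entrez number and symbol, and 35 of them were at 0 in all libraries. FPKM divides each gene by a library total, so a large fall in one set of genes raises the others, and the values do not show how much RNA a cell held. The FPKM values summed to between 417829 and 434167 per siControl library and to between 446246 and 459595 per siOXTR library. Sequencing depth is unknown. Low values were searched for the steps that whole fragments would leave, with transcript lengths from GENCODE release 29, and the best fit differed between libraries and reached a coherence between 0.101 and 0.187 of a possible 1, so no depth was taken from them. Genes with near-identical copies (NOMO1, NOMO2 and NOMO3, SMIM11A and SMIM11B, and the histone genes) may share reads, and their single values are uncertain.

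Because the files hold FPKM, a count model was not used. Genes with a mean of at least 1 FPKM over the 6 libraries (11550 genes) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model with group as the only term, moderated variances with a mean trend and a robust prior, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. Folds given as "-fold" are ratios of mean FPKM. Values with ± are the mean and SD of 3 libraries.

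A set of 31 gene lists was fixed before the data were examined. These cover YAP/TAZ target genes, Hippo pathway components, oxytocin receptor and Gq signalling, ERK pathway output, immediate early genes, DNA replication and G1/S genes, mitotic genes, p53 target genes, apoptosis regulators, the type I interferon response, NF-kB and cytokine genes, the unfolded protein response, ATF4 target genes, cholesterol biosynthesis, glycolysis and hypoxia response, oxidative phosphorylation, mesenchymal and EMT genes, epithelial adhesion and junction genes, integrins with focal adhesion and actin regulators, TGF-beta, Wnt and Notch target genes, gastric and intestinal lineage genes, ERBB receptors and ligands, autophagy and lysosome genes, small RNA machinery, cytoplasmic ribosomal proteins, replication-dependent histone genes, mitochondrially encoded genes, fibroblast markers, and blood and endothelial markers. The 28 lists with at least 5 tested members were tested with limma's camera, which compares a list with all other tested genes, at a preset correlation between genes of 0.01, and adjusted over the 28 lists. Each was tested again with a correlation estimated from the libraries. That version also takes its degrees of freedom from the libraries and not from the number of genes, so its p-values can rise without any correlation. Each was also tested with fry, which asks whether the members move one way on balance. Single genes were named by a rule fixed at the same time. It takes OXTR, then YAP1, WWTR1, CCN1, CCN2, ANKRD1, AXL and LATS2, then the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 5 FPKM and no overlap between groups, and finally up to 4 members of each list past the threshold with the largest change. Other members and genes named in the text were chosen after their values were seen.

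After the values had been seen, each gene's protein was sorted by a simple prediction from its main coding transcript in GENCODE release 29, matched by Entrez number. A protein was taken as secreted or membrane-bound if a 9-residue window in its first 35 residues had a mean Kyte-Doolittle hydropathy of at least 2.2 or if any 19-residue window reached 1.7. A protein whose single such window lay within 45 residues of its end was set apart as tail-anchored. This prediction makes errors in both directions, and 5 of 39 cytoplasmic ribosomal protein genes were counted as secreted or membrane-bound by it. Random lists (10000 per gene list) were drawn from tested genes matched on this class, on 5 bins of coding length and on 5 bins of expression. Their genes were drawn independently, so the comparison takes no account of correlation between the members of a gene list. All 7-mers were tested in annotated 3' UTRs for a relation to the log2 fold change, in a linear model with class, coding length, their interaction, UTR length and GC content. Gene positions are those of GENCODE release 29 on GRCh38. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for these steps, and figures were drawn with matplotlib 3.10.9.

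The test was tried on simulated data for this comparison, with 11550 genes of which 200 were changed. It recovered 98% of the genes changed by 1 and 92% of those changed by 0.5 on the log2 scale, with 7 false calls. The planted changes were balanced in direction, left out the lowest genes and came with independent normal noise. No shift in scaling between groups was planted. In the real data 59.8% of tested genes passed and the median moved, so these rates check the code and do not describe the real comparison. Alternatives were a replicate block, each library left out in turn, TMM scaling computed on the FPKM values, limma with no trend and no robust prior, no filter on low values, a minimum mean of 5 FPKM, a pseudocount of 0.1, a test against a 1.5-fold change and array weights. Scaling to genes with no predicted segment, counts over those genes alone, other hydropathy thresholds and the Gq signalling list without OXTR were added after the data were seen.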

Results

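The series measured mRNA in SNU216 cells, a gastric cancer cell line, after siRNA transfection for 48 h. It compared 3 siOXTR libraries with 3 siControl libraries, and its title concerns the oxytocin receptor and YAP, the transcriptional co-activator restrained by the Hippo pathway. Each library listed 17318 genes as FPKM, of which 11489 to 11555 reached 1 FPKM. Libraries of one group correlated at a Pearson r of 0.995 to 0.998 over the 11550 tested genes, and libraries of different groups at 0.974 to 0.976. The first principal component held 83.1% of the variance and separated the groups. No pair of libraries of one group had the same value in more than 0.606% of tested genes, so each was counted as 1 replicate. Depth was not known, and no batch was labelled. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, and an exact test of 3 against 3 could give no p below 0.1.

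OXTR, the receptor for the peptide oxytocin, was at 39.1 ± 0.257 FPKM in siControl and 4.92 ± 0.371 FPKM in siOXTR (SD, n = 3 each), a fall of 7.95-fold. It lies on chromosome 3 from 8750408 to 8769628 (GRCh38). The siControl libraries held 39.37, 38.87 and 39.02 FPKM and the siOXTR libraries 4.76, 4.65 and 5.34 FPKM. Its log2 fold change of -2.76 (SE 0.061, adjusted p = 6.39e-11, limma) was the lowest of all tested genes. OXTR expression thus followed the labels in every library.

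Other genes fell almost as far. TNC, which encodes the matrix protein tenascin C, went from 28.2 ± 1.75 to 4.57 ± 0.224 FPKM, and the complement gene C3 from 279 ± 9.04 to 55.6 ± 2.71 FPKM. THBS1 (thrombospondin 1), one of the most abundant of these, went from 1550 ± 40.2 to 395 ± 7.52 FPKM. The 12 largest falls under the naming rule included OXTR, CCN2, the protease genes ECE1, CTSC, ADAM9 and ANPEP, the glucose transporter gene SLC2A3, and NOMO1 and NOMO2, whose copies are nearly identical. The largest rise was in the metallothionein gene MT1F, from 5.14 ± 0.323 to 17.5 ± 1.41 FPKM. HMOX1, which encodes haem oxygenase, rose from 14.1 ± 0.373 to 41.2 ± 2.34 FPKM, and ASNS, asparagine synthetase, from 11.9 ± 0.645 to 32.1 ± 2.58 FPKM. MT1E rose 2.48-fold, the stress-induced transcription factor gene DDIT3 2.28-fold, S100P 2.10-fold, GSTZ1 2.14-fold and OSGIN1 2.08-fold. The histone genes H2BC11, H2BC9 and H4C15 and the gene SMIM11B completed the 12 rises, and each of these has close copies.

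Of the 11550 tested genes, 6905 changed (limma, adjusted p under 0.05), with 4869 higher and 2036 lower in siOXTR. Large changes were mostly falls, since 270 genes fell by 1 or more on the log2 scale and 8 rose by as much. The groups did not overlap in 64.4% of tested genes, against 10% by chance for 3 libraries against 3. The direction of small changes depended on scaling. The median log2 fold change of all tested genes was 0.13 as deposited and 0.013 after TMM scaling, a shift of -0.115, and TMM scaling gave 2213 genes higher and 2829 lower. All 2036 genes called lower as deposited were also lower after TMM scaling, whereas 2656 of those called higher were not higher after it. A downward shift could hardly undo a fall, so this contrast does not show that the falls are firmer than the rises.

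The falls were concentrated in genes whose proteins are predicted to be secreted or to cross a membrane, a class defined after the data were seen. Of the 270 genes that fell by 1 or more, 258 (95.6%) belonged to it, against 28.9% of all tested genes. Its 3337 genes had a median log2 fold change of -0.12 and the 7964 genes with no predicted segment a median of 0.17, a gap of -0.30 (95% bootstrap interval over genes -0.32 to -0.28). In the first class 1530 genes fell and 683 rose, and in the second 478 fell and 4065 rose. After TMM scaling 1779 genes were lower and 286 higher in the first class, and 1015 lower and 1852 higher in the second. The first class held 26.1% to 26.5% of the FPKM of tested genes in siControl and 19.7% to 20% in siOXTR. Genes of mitochondrial proteins picked by symbol, also after the data were seen, did not share the fall, with a median of 0.29 among the 52 of them with a predicted segment. Because many of the gene lists contain such genes, the medians of their predicted secreted or membrane members and of their other members are given separately for the lists that camera called lower.

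**Figure D1:**
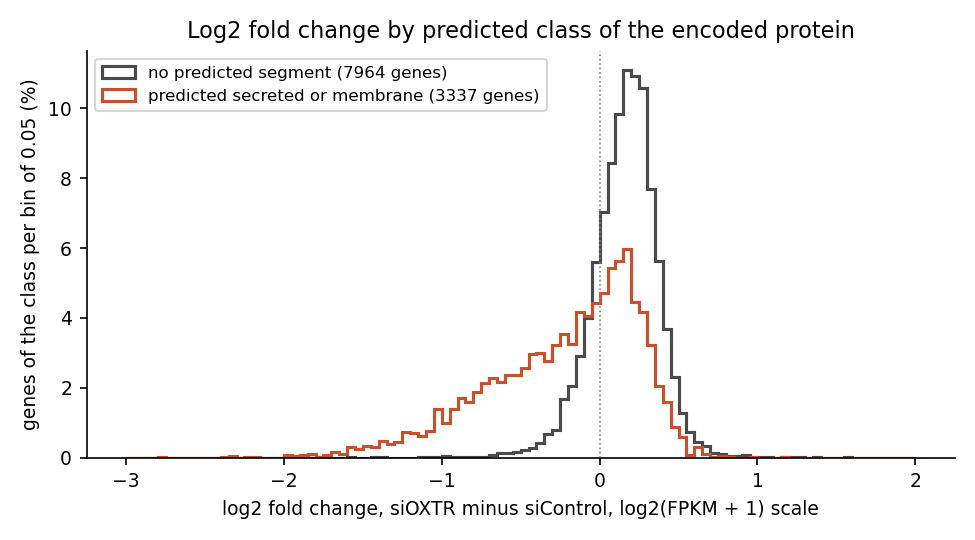
Log2 fold change (siOXTR minus siControl, log2(FPKM + 1) scale, horizontal axis) against the percent of genes of each class per bin of 0.05 (vertical axis). The 7964 genes with no predicted segment form a single peak around a median of 0.17, and the 3337 predicted secreted or membrane genes, with a median of -0.12, have a long tail towards lower values.

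YAP/TAZ target genes were lower in siOXTR. Of 21 tested genes, 14 fell and 4 rose, and the counts adjusted over the list alone were the same. CCN2 (CTGF) went from 15.9 ± 0.691 to 3.38 ± 0.161 FPKM and CCN1 (CYR61) from 134 ± 2.38 to 47.1 ± 2.34 FPKM, both of them secreted matrix-associated proteins. The receptor tyrosine kinase gene AXL fell from 96.4 ± 2.95 to 35.7 ± 1.46 FPKM and CCDC80 from 13.9 ± 0.556 to 4.65 ± 0.182 FPKM. ANKRD1, a nuclear cofactor gene, fell less, from 35.1 ± 1.21 to 27.3 ± 1.63 FPKM, and LATS2, a Hippo kinase gene and YAP target, from 13.1 ± 0.369 to 10.0 ± 0.442 FPKM. AMOTL2, MYOF, GADD45A and DOCK5 rose, of which 1 remained higher after TMM scaling. The list's median log2 fold change was -0.36, with a camera adjusted p of 9.72e-08. With an estimated correlation the adjusted p was 0.0415, and fry gave an FDR of 5.86e-06. Its 11 predicted secreted or membrane members had a median of -1.25 and its other 10 members a median of -0.16. Within the predicted class DOCK5 and ARHGEF17 had log2 fold changes of 0.30 and 0.14, and every other member was at -0.71 or lower. Outside it F3, set apart as tail-anchored, was at -1.10, and the rest lay between -0.36 (LATS2) and 0.25 (GADD45A). The large falls of this list were thus confined to the predicted class and F3.

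YAP1 itself, on chromosome 11 from 102110461 to 102233423, was slightly lower, at 80.4 ± 3.79 FPKM in siControl and 68.4 ± 0.498 FPKM in siOXTR (log2 fold change -0.23, SE 0.052, adjusted p = 0.00271, limma). WWTR1, which encodes TAZ, was at 36.1 ± 2.88 and 39.4 ± 0.759 FPKM and did not pass the threshold (adjusted p = 0.0939), though it did without siControl replicate 3 (log2 fold change 0.19, adjusted p = 0.0121). After TMM scaling the log2 fold change was 0.00034 for WWTR1 (adjusted p = 0.997, limma) and -0.36 for YAP1 (adjusted p = 0.000186, limma). Among the 26 tested Hippo pathway components 8 rose and 4 fell, or 7 and 3 adjusted over the list alone, and after TMM scaling 1 was higher and 9 were lower. LATS1 went from 8.30 ± 0.756 to 11 ± 0.836 FPKM, and SAV1 and TEAD1 fell by 0.21 and 0.16 on the log2 scale. The list's median was 0.022 and its camera adjusted p was 0.593. Camera placed it below the other genes and fry, which found no balance in one direction (FDR 0.394), above 0.

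**Figure D2:**
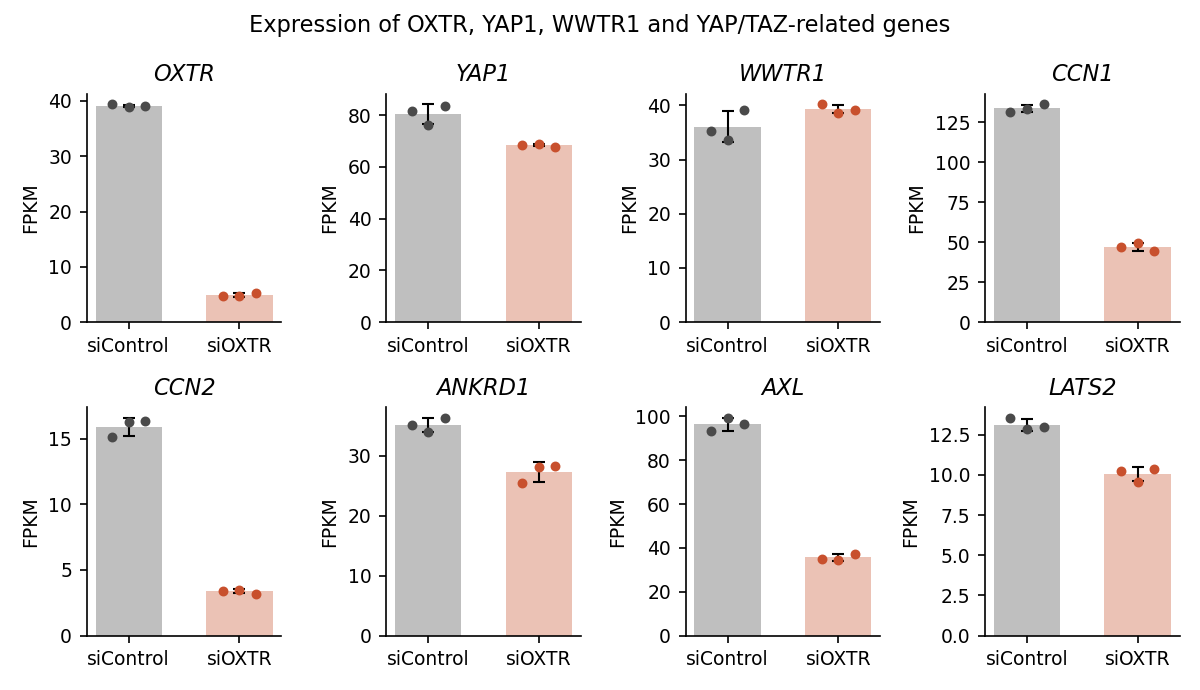
FPKM (vertical axis, starting at 0) of OXTR, YAP1, WWTR1 and 5 YAP/TAZ-related genes in siControl and siOXTR. Points are the 3 libraries of a group, bars their means and error bars their SDs. OXTR, CCN1, CCN2 and AXL fell by 2.70-fold or more, YAP1, ANKRD1 and LATS2 by 1.31-fold or less, and WWTR1 did not pass the test.

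The integrin and focal adhesion list and the mesenchymal and EMT list fell, and by more than genes matched on predicted class, coding length and expression. Among integrins, laminins, focal adhesion and actin regulators 26 of 32 tested genes fell and 2 rose (median -0.48, camera adjusted p = 1.53e-15, adjusted p = 0.0523 with an estimated correlation). ITGB4, the integrin of hemidesmosomes, fell from 185 ± 4.48 to 54.5 ± 1.97 FPKM, and LAMA3, which encodes a chain of its laminin ligand, fell 3.36-fold. Its 18 predicted secreted or membrane members had a median of -1.21 and the other 14 a median of -0.16. The central 95% of matched random lists had medians from -0.088 to 0.16 for this list and from -0.38 to 0.19 for the mesenchymal and EMT list. Of 23 listed mesenchymal and EMT genes 13 were tested, and CDH2, SNAI1, ZEB1, ZEB2 and MMP2 were not among them. Of the 13, 9 fell and 2 rose (median -1.02, camera adjusted p = 2.66e-07, adjusted p = 0.0415 with an estimated correlation). MMP14, a membrane-bound matrix protease gene, fell 3.03-fold, and FN1 (fibronectin), which was low in both groups, from 3.84 ± 0.427 to 0.640 ± 0.0265 FPKM. The 9 predicted secreted or membrane members of that list had a median of -1.18 and the other 4 a median of -0.16.

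Epithelial adhesion genes moved both ways, with 13 of 29 lower and 9 higher, or 13 and 10 adjusted over the list alone, and 13 lower and 1 higher after TMM scaling. CDH1, which encodes E-cadherin, fell from 76.1 ± 3.28 to 20 ± 0.243 FPKM, and DSG2, ST14 and CLDN1 fell 3.19-fold, 2.56-fold and 2.06-fold. The median of the list was 0.032 and its mean -0.27. Camera placed it below other genes (adjusted p = 0.00354, adjusted p = 0.121 with an estimated correlation). Its 14 predicted secreted or membrane members had a median of -0.73 and the other 15 a median of 0.15. The list was not lower than lists matched on predicted class, coding length and expression (0.21 of them had a median as low, adjusted p = 0.471).

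Several lists of signalling pathways were lower. TGF-beta target genes had 10 of 16 lower and 4 higher (median -0.32, camera adjusted p = 0.000215, adjusted p = 0.0523 with an estimated correlation), and their 9 predicted secreted or membrane members had a median of -0.82 against 0.23 for the other 7. Among them TGFBI fell 2.36-fold, and ID1 rose by 0.81 on the log2 scale. Of 20 listed Wnt target genes 9 were tested, and AXIN2, LGR5, RNF43, LEF1, NOTUM and SP5 were not among them. Of the 9, 8 were lower (median -0.24, camera adjusted p = 5.75e-05, adjusted p = 0.0523 with an estimated correlation). They were led by the receptor genes EPHB2, which fell 3.00-fold, and CD44, which fell 2.05-fold. Medians were -0.82 for 4 predicted secreted or membrane members and -0.21 for the 4 others with a prediction, among them CCND1 and SOX4, which fell by 0.23 and 0.24 on the log2 scale. Of 15 listed Notch genes 8 were tested, of which 6 fell and 2 rose (median -0.78, camera adjusted p = 0.000293, adjusted p = 0.116 with an estimated correlation). The falls included the receptor genes NOTCH3 (3.73-fold), NOTCH2 (2.52-fold) and NOTCH1 (2.45-fold) and the ligand gene JAG2 (2.25-fold), whereas HES1, a transcription factor gene induced by Notch, rose by 0.34 on the log2 scale. The 5 predicted secreted or membrane members had a median of -1.08 and the other 3 a median of 0.17. ERBB receptors and ligands had 8 of 13 lower and none higher (median -0.28, camera adjusted p = 3.22e-05, adjusted p = 0.0523 with an estimated correlation). EGFR fell from 54.7 ± 3.90 to 26.3 ± 1.43 FPKM, ERBB2 from 182 ± 20.1 to 101 ± 5.62 FPKM and AREG, an EGFR ligand gene, from 90.2 ± 8.83 to 35.3 ± 1.28 FPKM. Its 11 predicted secreted or membrane members had a median of -0.35 and the other 2 a median of 0.048. The ERBB list was not lower than lists matched on predicted class, coding length and expression (0.068 of them had a median as low, adjusted p = 0.173).

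**Figure D3:**
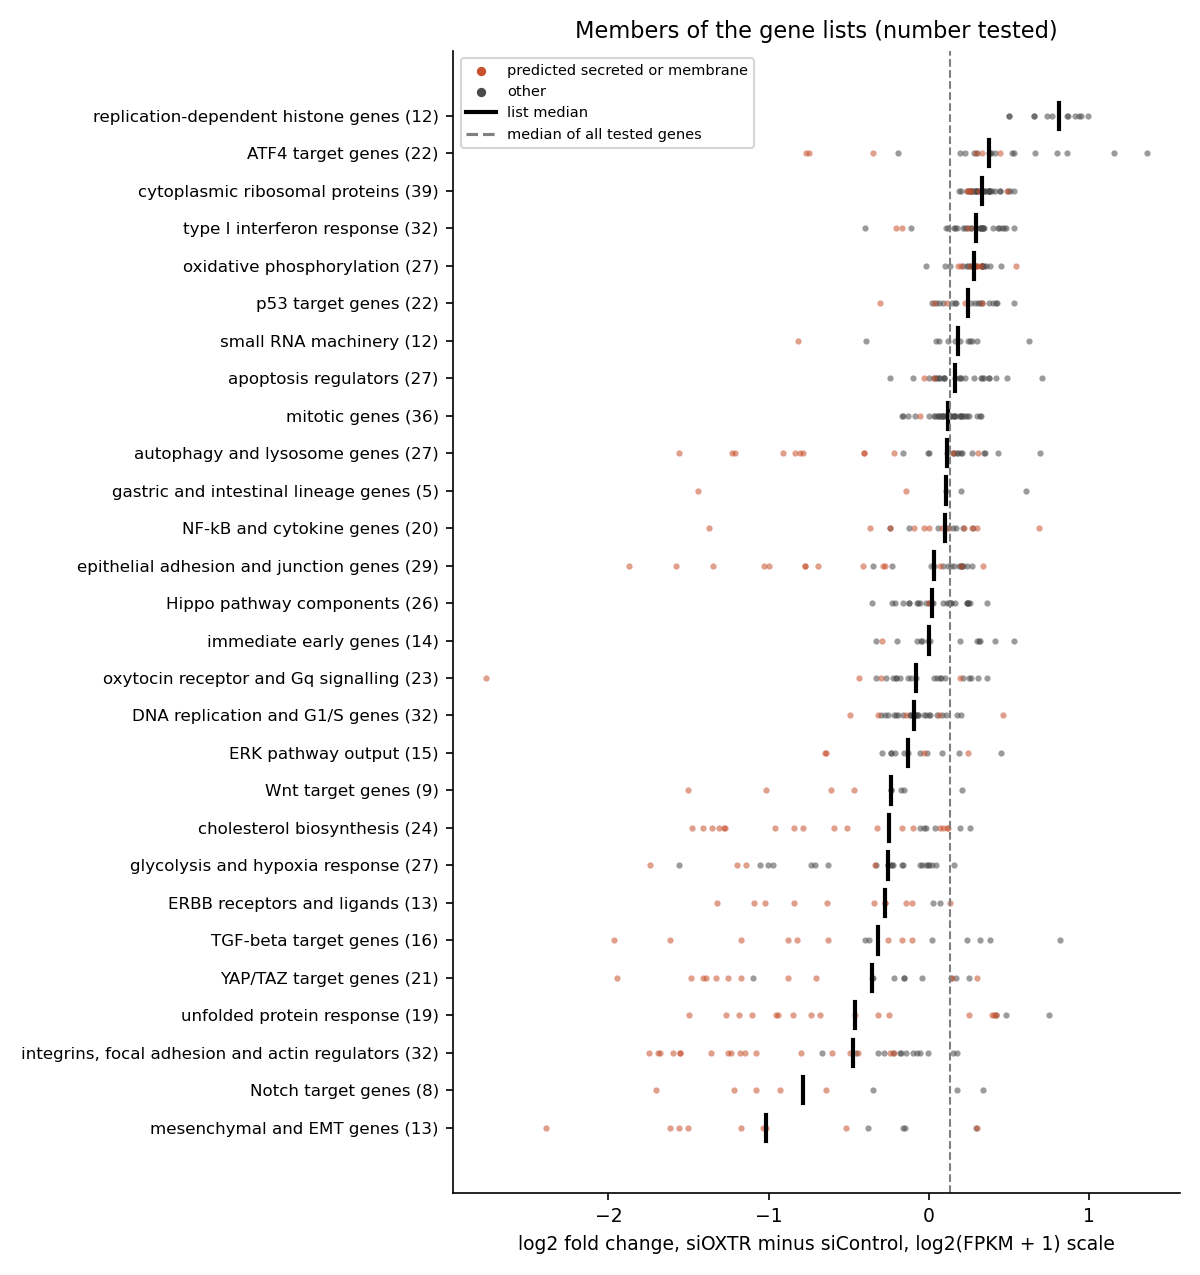
Log2 fold change (siOXTR minus siControl, log2(FPKM + 1) scale, horizontal axis) of the tested members of 28 gene lists (rows, number tested in parentheses). Each point is a gene, coloured by whether its protein is predicted to be secreted or membrane-bound, the black bar is the list median and the dashed line the median of all tested genes (0.13). Medians run from -1.02 for mesenchymal and EMT genes to 0.81 for replication-dependent histone genes, and most of the far left points belong to the predicted class.

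Genes of the endoplasmic reticulum changed in both directions. In the unfolded protein response list all 19 genes passed the threshold, 12 lower and 7 higher (median -0.46, camera adjusted p = 0.000293, adjusted p = 0.0702 with an estimated correlation). The chaperone genes HSP90B1 (763 ± 22.4 to 270 ± 10.5 FPKM), HSPA5 (413 ± 8.33 to 172 ± 6.22 FPKM), HYOU1 and PDIA4 fell most, while HERPUD1 rose by 0.75 and the transcription factor gene XBP1 by 0.48 on the log2 scale. The other 5 rises were those of the chaperone and cofactor genes DNAJB9 (0.25), SDF2L1 (0.39), MANF (0.41) and CRELD2 (0.42), all of the predicted secreted or membrane class, and of SEC61B (0.42), and after TMM scaling DNAJB9 did not pass the threshold. The 16 predicted secreted or membrane members had a median of -0.71 and the other 3 a median of 0.48. Of 22 tested ATF4 target genes 18 rose and 4 fell, with 12 higher after TMM scaling (median 0.38, camera adjusted p = 0.0116, adjusted p = 0.0969 with an estimated correlation). ATF4 went from 120 ± 0.568 to 219 ± 10.9 FPKM, and ASNS and DDIT3 were among the largest rises of all genes. STC2, SLC7A1 and SLC7A5, which encode a secreted protein and amino acid transporters, fell by 0.77, 0.75 and 0.35 on the log2 scale, and DDIT4, with no predicted segment, by 0.20. SLC3A2, GDF15 and SLC7A11, of the predicted secreted or membrane class, rose by 0.44, 0.33 and 0.29 as deposited, and of these SLC3A2 alone passed the threshold after TMM scaling.

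Cholesterol biosynthesis genes had 12 of 24 lower and 2 higher (median -0.25, camera adjusted p = 7.95e-07, adjusted p = 0.0415 with an estimated correlation). SQLE, which encodes squalene epoxidase, fell 2.65-fold. The cytosolic enzyme genes HMGCS1 and FDPS had log2 fold changes of -0.03 and -0.02 and did not pass the threshold. Medians were -0.69 for 18 predicted secreted or membrane members and 0.012 for the other 6. The list was not lower than lists matched on predicted class, coding length and expression (0.0441 of them had a median as low, adjusted p = 0.123). Of 27 autophagy and lysosome genes 12 rose and 10 fell, or 13 and 11 adjusted over the list alone, and 5 were higher and 11 lower after TMM scaling. The lysosomal membrane genes LAMP1 and LAMP2 fell 3.00-fold and 2.45-fold and the hydrolase gene CTSD 1.89-fold, whereas SQSTM1, an autophagy receptor gene, rose by 0.69 on the log2 scale. That list had a median of 0.11, a mean of -0.18 and a camera adjusted p of 0.0845.

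Glycolysis and hypoxia response genes fell, including those with no predicted segment. Of 27 tested genes 19 fell and 1 rose (median -0.25, camera adjusted p = 1.88e-09, adjusted p = 0.0523 with an estimated correlation). P4HA1, a collagen prolyl hydroxylase gene, fell from 45.5 ± 1.06 to 12.9 ± 0.623 FPKM, NDRG1, a cytosolic protein gene induced by hypoxia, from 30.9 ± 1.23 to 9.81 ± 0.816 FPKM, and the glucose transporter gene SLC2A1 and the peptide hormone gene ADM 2.31-fold and 2.23-fold. ANKRD37, PFKFB4 and ALDOC fell by 1.06, 1.01 and 0.97 on the log2 scale. VEGFA had a log2 fold change of 0.02 and did not pass the threshold. Its 4 predicted secreted or membrane members had a median of -1.17 and the other 23 a median of -0.23. Oxidative phosphorylation genes were higher in 24 of 27 cases and lower in none, and after TMM scaling in 12, with 1 lower (median 0.28, camera adjusted p = 0.000215, adjusted p = 0.274 with an estimated correlation). NDUFA4 rose 1.47-fold.

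Signalling lists close to OXTR changed little in size. In the oxytocin receptor and Gq signalling list 9 of 23 genes fell and 5 rose (median -0.083, camera adjusted p = 0.0457, adjusted p = 0.194 with an estimated correlation), and after TMM scaling 12 were lower and 2 higher. The list holds OXTR itself, and without it 8 of 22 genes fell and 5 rose (median -0.025, mean -0.026), and the camera call was lost (adjusted p = 0.128). Medians of the full list were -0.37 for 4 predicted secreted or membrane members and 0.033 for the other 19. The call of the full list was also lost without siControl replicate 1 (adjusted p = 0.0795), siControl replicate 2 (0.0505), siOXTR replicate 2 (0.058) or siOXTR replicate 3 (0.0522). Apart from OXTR, the calcium channel gene ITPR3 fell from 33.0 ± 1.59 to 24.1 ± 1.73 FPKM, the kinase gene ROCK1 from 14.5 ± 1.00 to 11.3 ± 0.0802 FPKM, and CAMK2G rose from 21.7 ± 0.255 to 28.1 ± 0.280 FPKM. ERK pathway output genes had 7 of 15 lower and 3 higher, or 8 and 3 adjusted over the list alone, and 9 lower and 1 higher after TMM scaling (median -0.13, camera adjusted p = 0.0279, adjusted p = 0.121 with an estimated correlation). The receptor genes EPHA2 and EPHA4 fell 1.61-fold and 1.88-fold, ETV4 1.26-fold, and SPRY2 rose 1.43-fold. Medians were -0.34 for 4 predicted secreted or membrane members and -0.092 for the others with a prediction. This call was lost with a minimum mean of 5 FPKM (adjusted p = 0.160). Immediate early genes had 6 of 14 higher and 3 lower, and 5 higher and 5 lower after TMM scaling (median -0.00084, mean 0.076, camera adjusted p = 0.835), with ZFP36 1.47-fold and FOS 1.61-fold higher and SRF 1.28-fold lower.

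Proliferation genes were divided. DNA replication and G1/S genes had 10 of 32 lower and 3 higher, and 23 lower after TMM scaling (median -0.091, camera adjusted p = 0.00155, adjusted p = 0.0523 with an estimated correlation). Medians were -0.15 for 5 predicted secreted or membrane members and -0.089 for the other 27. The 5 include MCM3, CCNE1 and RRM2, which are not secreted or membrane proteins, so the split of this list shows errors of the prediction. MCM3 and MCM6, subunits of the replicative helicase, fell 1.42-fold and 1.24-fold and CCNE1 1.27-fold, whereas RRM2 rose 1.39-fold. Mitotic genes had 17 of 36 higher and 1 lower, or 16 and 1 adjusted over the list alone, but 3 higher and 5 lower after TMM scaling (median 0.12, camera adjusted p = 0.185). All 12 tested replication-dependent histone genes rose (median 0.81, camera adjusted p = 5.75e-05, adjusted p = 0.0523 with an estimated correlation), 11 of them after TMM scaling. Among them H2BC12 went from a mean of 57.5 to 105 FPKM, and H3C10, low in both groups, from 1.54 ± 0.362 to 3.86 ± 0.116 FPKM. p53 target genes had 13 of 22 higher and 1 lower, with 8 higher after TMM scaling (median 0.24, camera adjusted p = 0.0457, adjusted p = 0.129 with an estimated correlation). CDKN1A, the p21 gene, rose 1.33-fold, BAX 1.34-fold and SESN2 1.48-fold. The camera call was lost without siControl replicate 1 (adjusted p = 0.0557) or siOXTR replicate 2 (0.0541). Apoptosis regulators had 13 of 27 higher and 1 lower, with 9 higher after TMM scaling (median 0.16, camera adjusted p = 0.0991), led by PMAIP1 (41.4 ± 6.22 to 67.6 ± 1.84 FPKM) and CASP9 (1.46-fold).

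Type I interferon response genes were higher in 26 of 32 cases and lower in 3, or 27 and 3 adjusted over the list alone, with 16 higher after TMM scaling (median 0.29, camera adjusted p = 0.00135, adjusted p = 0.121 with an estimated correlation). CMPK2 rose 1.46-fold, IRF7 1.40-fold and OASL 1.37-fold. NF-kB and cytokine genes had 6 of 20 higher and 4 lower, or 6 and 3 adjusted over the list alone, but 2 higher and 6 lower after TMM scaling (median 0.098, camera adjusted p = 0.792). The adhesion receptor gene ICAM1 fell 2.66-fold and the chemokine gene CXCL2 rose 1.65-fold. All 39 cytoplasmic ribosomal protein genes were higher, 22 of them after TMM scaling (median 0.33, camera adjusted p = 4.39e-06, adjusted p = 0.334 with an estimated correlation of 0.489 between members). The small RNA machinery had 7 of 12 higher and 2 lower, with 2 higher and 2 lower after TMM scaling (median 0.18, camera adjusted p = 0.615). DICER1 rose 1.58-fold and XPO5 fell 1.81-fold.

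Of 32 gastric and intestinal lineage genes 5 could be tested, of which 2 rose and 1 fell as deposited, and 1 was higher and 2 were lower after TMM scaling (median 0.11, mean -0.13, camera adjusted p = 0.593). The mucin gene MUC1 fell from 11.4 ± 1.46 to 3.55 ± 0.138 FPKM, and PSCA was low in both groups, at 1.11 ± 0.146 and 2.22 ± 0.204 FPKM. One of 14 fibroblast markers was tested, POSTN, at 1.09 ± 0.0907 and 1.02 ± 0.0551 FPKM (adjusted p = 0.624), and 1 of 16 blood and endothelial markers, CD68, at 8.61 ± 0.766 and 7.40 ± 0.0577 FPKM (adjusted p = 0.0296). None of the 13 mitochondrially encoded genes was found by symbol among the deposited genes, so this list could not be tested.

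At the preset correlation camera called 20 of 28 lists, 14 lower and 6 higher than other genes, among them the Gq signalling list, whose call rested on OXTR. With an estimated correlation 3 lists passed, namely YAP/TAZ target genes, cholesterol biosynthesis and mesenchymal and EMT genes. Counts adjusted over the list alone equalled those over all genes for 21 of the 28 lists.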

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

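The fall of OXTR and of the YAP/TAZ target gene list kept its direction and its side of the threshold under all alternatives run. The log2 fold change of OXTR lay between -2.81 and -2.73 with a library left out and between -2.97 and -2.76 otherwise, and the median of the YAP/TAZ list between -0.38 and -0.35 and between -0.54 and -0.35 (adjusted p from 1.95e-08 to 0.0415, the latter with an estimated correlation). Counts depended more on the settings. With a library left out, 5812 to 6699 genes changed, 3980 to 4671 higher and 1820 to 2028 lower. TMM scaling gave 2213 higher. A test against a 1.5-fold change gave 460 genes changed, 16 higher and 444 lower, as a stricter threshold must, and cannot be run on lists. Among alternatives chosen after seeing the data, scaling to genes with no predicted segment gave 1304 higher and 3438 lower, and those genes alone gave 4543 changed and 478 lower, since 1530 of the 2036 genes called lower lie in the excluded class. The oxytocin receptor and Gq signalling list, called with OXTR in it, was not past the threshold without OXTR (adjusted p = 0.128), also an alternative added later. The share of higher genes was 70.5% as deposited, 43.9% after TMM scaling and 27.5% after scaling to genes with no predicted segment. TMM scaling also divides each library by its FPKM total. Those totals were higher in every siOXTR library (446246 to 459595) than in every siControl library (417829 to 434167). Dividing by them lowers siOXTR values relative to siControl values. The rest of the difference between scalings was not traced, and FPKM alone cannot say which scaling is right.

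The gap between predicted secreted or membrane genes and other genes was -0.43 with stricter and -0.23 with looser hydropathy thresholds. In the 1.5-fold test, a stricter threshold, 66 of 128 named genes other than OXTR passed and 61 lost their call. Of the 128, 13 lost their call in at least 1 setting besides that test. All 13 were rises lost after scaling to genes with no predicted segment (STK3 went from 0.26 to 0.066), and none of these changed sign. That scaling moved values down, so it could hardly undo a fall. Of 20 called lists, 17 lost the call with an estimated correlation. Correlation between members does not account for all of these losses. The Wnt list had an estimated correlation of -0.067, below the preset 0.01, and its unadjusted camera p still went from 1.85e-05 to 0.0112. The replicate block gave 7205 genes changed, 5100 higher and 2105 lower, and changed no other call. Libraries with the same number deviated from their group means with correlations of 0.107, 0.00421 and 0.16, and siControl 2 correlated best with siOXTR 1 (0.208), so the numbers were not taken to pair the libraries. Depth is unknown, so no limit for low genes can be given.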

Other observations

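The tests of coding length and GC content, of RNA loss at harvest, of 3' UTR 7-mers in the YAP/TAZ list, of all 7-mers tied to lower expression together, the prediction of secreted or membrane proteins and the extra lists named here were chosen after the results were seen. Most tested genes on added lists of NRF2 targets and of metallothioneins rose. The lists of NRF2 targets and metallothioneins were drawn up after members of them (HMOX1 and OSGIN1, MT1F and MT1E) had been seen among the 12 largest rises, so their counts describe the data and no p is given for them. Of 21 tested genes on a list of NRF2 targets, NRF2 being the regulator of antioxidant genes, 20 were higher in siOXTR and none lower, with 16 higher and 1 (ABCC3) lower after TMM scaling (median 0.57). HMOX1 rose 2.92-fold, and NQO1 went from 198 ± 7.92 to 320 ± 4.02 FPKM, TXNRD1 from 104 ± 4.91 to 160 ± 3.68 FPKM and GCLC from 47.6 ± 2.06 to 75.8 ± 2.32 FPKM. The ferritin genes FTH1 and FTL rose 1.57-fold and 1.64-fold, and FTH1 took 1.18% to 1.39% of all FPKM in siControl and 1.9% to 1.99% in siOXTR. ABCC3, at 15.1 ± 0.760 and 14.6 ± 0.983 FPKM, did not pass the threshold as deposited. All 5 tested metallothionein genes, which bind zinc and copper, were higher, 4 of them after TMM scaling (median 0.67). MT2A rose from 333 ± 11.6 to 519 ± 17.7 FPKM.

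Genes of the machinery that brings mRNAs to the endoplasmic reticulum moved both ways. Among 18 genes of the signal recognition particle and the translocon, 7 rose and 8 fell, with 3 higher and 9 lower after TMM scaling (median -0.064, camera adjusted p = 0.0460 over the 3 lists drawn up after the data were seen, adjusted p = 0.350 with an estimated correlation). The 16 members that could be matched were not lower than random lists matched on predicted class, coding length and expression. Of those lists 0.0369 had a median as low (adjusted p = 0.0738 from the matched lists). The genes of the particle, SRP9, SRP14, SRP19, SRP54, SRP68 and SRP72, rose by 0.16 to 0.32 on the log2 scale as deposited, but after TMM scaling only SRP19 (adjusted p = 0.02) and SRP68 (0.0451) of these passed the threshold. SEC61A1 fell from 97.7 ± 3.66 to 52.9 ± 0.333 FPKM and SEC63 from 34.5 ± 0.952 to 16.5 ± 0.512 FPKM, and both encode membrane proteins themselves.

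The lower level of mRNAs for predicted secreted and membrane proteins was weighed against several explanations. Coding length and GC content are argued against as the cause, since the gap within 20 bins of both was 1.06 times the full gap and negative in each bin (-0.49 to -0.12). Off-target silencing through the siRNA seed stays open, because the siRNA sequences are not given and which 7-mer is the seed is not known. The 7-mer most strongly tied to lower expression among 16113 tested, ACTTTCA, occurs in the coding part of OXTR. Genes with it in the 3' UTR were lower by a coefficient of -0.094 over 11183 genes, 1535 of which carry it. Its t in the linear model was -10.5. CTTTCAA, which shares CTTTCA with it, came next at -7.96, and TATTTTT, which does not, followed at -6.14. ACTTTCA and CTTTCAA thus stood apart from the other 7-mers, as a seed effect of an OXTR siRNA could produce. The place of ACTTTCA in OXTR adds little by itself, since 22% of tested 7-mers occur in the OXTR transcript. CTTTCAA does not occur there. Among genes lacking ACTTTCA the gap was 0.946 of that among all genes searched. Among the 3624 genes lacking all 8 7-mers tied to lower expression the gap was 0.787 of it. The 8 are not separate motifs, since CTTTCAA, CTTTCAT and GACTTTC overlap ACTTTCA. These values argue against silencing through these 7-mers in each gene's own 3' UTR as the whole cause. They say nothing of a seed not among them, nor of effects that pass through another silenced gene. Loss of RNA bound to the endoplasmic reticulum at harvest stays open. It needs nearly all abundant members of the class to be lower, and 73 of the 100 most abundant predicted genes lay below the median of other genes where 95 were required. Of the 100, 60 were called lower and 29 higher as deposited, with 12 higher after TMM scaling, and errors of the prediction could make fewer of them low. An unfolded protein response stays open too, because 0.0312 of matched random lists had a median at or below that of the list, in neither tail, and its members split into 12 that fell and 7 that rose, with chaperone genes on both sides. No test here separates an effect of losing OXTR on these mRNAs from an effect of the siRNA or of the harvest.

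The YAP/TAZ target gene list may be low only through this general fall, as 11 of its 21 members belong to the predicted class. Only 0.0018 of random lists matched on class, coding length and expression had a median as low, which argues against the general fall as the whole cause. Since wrongly predicted genes dilute the matched lists, the 8 members with no predicted segment were also compared alone, and their median of -0.16 stood against a matched median of 0.15 (0.0004 of lists as low), a smaller difference than the full list shows. Seed matches cannot be told apart from an effect on YAP. LATS2, ANKRD1, CRIM1, CCDC80, TGFB2 and YAP1 itself carry the 7-mer, and a share of 0.0233 of matched lists had a median as low as the 14 list members without it, within the error of the draws around the 0.025 required, while the share was 0.0024 for the 6 members with neither feature.

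The fall of glycolysis and hypoxia response genes was not explained by the general fall of mRNAs of predicted secreted and membrane proteins, since 0.0001 of matched lists, the smallest share that 10000 draws can give, had a median as low, and the same share held for its 22 members with no predicted segment. A lower hypoxia response in siOXTR, or a difference in cell density or medium between the transfections, is a hypothesis that no value here tests. Over all 28 lists, 12 lay below and 5 above their matched lists after adjustment. Since the random genes were drawn independently, the shares can be too small for lists whose members vary together. The estimated correlation was 0.489 for ribosomal protein genes, 0.276 for oxidative phosphorylation, 0.162 for the Notch list and 0.151 for integrins and focal adhesion genes. Besides the YAP/TAZ and hypoxia lists, the lists below were mesenchymal and EMT genes, integrins and focal adhesion genes, TGF-beta and Wnt target genes and the Notch list. The others below were Hippo components, ERK output, immediate early genes, G1/S genes, and Gq signalling, which holds OXTR. In the Notch list 5 of 8 tested members, receptor and ligand genes, belong to the predicted class, and the other 3 had a median of 0.17. Not all of these 12 lists held in further comparisons. The TGF-beta members with no predicted segment were not low (share of matched lists as low 0.687), nor was the Wnt list with stricter classes (0.0478), and among members with neither a predicted segment nor the 7-mer the shares were 0.45 for immediate early genes, 0.0868 for Hippo components and 0.0563 for Gq signalling. Those above were interferon response, ATF4 target, oxidative phosphorylation, ribosomal protein and histone genes, of which oxidative phosphorylation genes with no predicted segment were not (0.942 of matched lists at or below, within the central 95%).

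Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The other splits each set 2 libraries of a group with 1 of the other, so they keep part of the difference. The real split gave 6905 genes changed, 4869 higher and 2036 lower, and the highest of the others gave 0 in each case (limma, with 28 to 231 genes at an unadjusted p under 0.05, against 7432 in the real split), so that 1 of 10 splits, the real one, was as large. Camera at the preset correlation called 20 lists in the real split and up to 16 in the others.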
